A study of Ephydatia fluviatilis with 7 samples.

How the data were processed

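The expression table and the coding sequences of the study were used as the authors deposited them. Per the labels' protocols, juvenile sponges were grown from gemmules of a single mother sponge. Archeocytes were marked with a mitochondrial dye and a DNA dye, choanocytes with the DNA dye and ingested fluorescent beads, and the other cells fraction with all of these, and cells were dissociated and sorted by fluorescence. RNA was extracted with a column kit, and 10 ng of total RNA per library was amplified with a SMARTer kit for very small RNA amounts, which keeps no strand information. Reads of overlapping reading frames on 1 contig can therefore not be told apart. Amplification from small amounts and the split of reads among near-identical sequences can both add error to the values of single sequences.

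The deposited values are RPKM per the file headers, for 17419 coding sequences predicted on the contigs of a transcriptome that was assembled in the same study, per the series' design text. The submitters' processing notes name RSEM 1.2.4, Bowtie and edgeR 3.0.0. The assembler and the tool that predicted the coding sequences are not given in the sources used here. In each library the RPKM values times coding length sum to between 999999.4 and 1000000.7, so each was scaled to its own total over these sequences. The authors' table also holds, per the file headers, log fold changes and FDR values, a kind of q-value, for 3 comparisons. Against the deposited RPKM the sign of these fold changes was the second-named fraction minus the first and their base was 2 (log2), with r between 0.991 and 0.995 and slopes between 1.076 and 1.091 over 8998 sequences with a mean of at least 10 RPKM. They are quoted only as the authors' deposited results.

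Low values were searched for the step that 1 read makes. Over sequences of up to 600 nt with at most 3 reads, between 67.4% and 70.7% of values per library lay within 0.1 reads of a whole number, so depth could be estimated. The values are not whole reads, and no test for counts was run except a limma voom fit, described below, as a check. The estimated depth is 10650000 to 13730000 reads per library. It counts reads assigned to the listed coding sequences and not all reads sequenced. Between 974 and 1429 sequences were listed at 0 in a library.

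The 6 sorted libraries fell into 3 fractions of 2, taken from the sample titles. Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3: 1 fit of group means over all 6 libraries, which leaves 3 residual degrees of freedom, with moderated variances that follow the mean, two-sided tests, and Benjamini-Hochberg adjustment within each comparison over the 14824 sequences with a mean of at least 1 RPKM. The other 2595 sequences were not tested. With 2 libraries against 2, an exact permutation test cannot reach 0.05, so none was run. A sequence counted as enriched in a fraction when it was higher at adjusted p under 0.05 than in both others. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

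The files do not pair identifiers with gene names, so 60 protein families in 10 groups were written down as residue signatures before the data were examined. The longest stop-free frame of each sequence, at least 60 residues long, was searched with each signature. In 99.2% of sequences this frame was the first forward frame. The same search in reversed residues gave the number of chance hits, and families whose chance hits exceeded 10% of their hits were left out of the list tests. This kept 36 families and left out 24, of which 3, Nanos, Wnt and the light-harvesting proteins of algae, had no hit. Stricter signatures for 8 of the families left out were added after the sequences, but not their expression, had been seen, and all 8 were kept. Chance hits of the added collagen signature were counted in shuffled residues instead of reversed ones, with 0 beside 17 hits. The planned collagen signature, left out, had 31 hits and also 31 in reversed residues. A list was tested where at least 5 of its sequences were tested, which gave 28 planned lists per comparison, 20 families and 8 groups of families, and 5 added ones. The list test was limma's camera with a preset correlation of 0.01 between sequences and, as a check, with the correlation estimated from the 6 libraries. The check takes its p from the 3 residual degrees of freedom, which makes it hard to pass. Fisher's exact test compared the enriched sets with the tested sequences. The 17419 sequences fell into 14439 loci by their identifiers, and 6711 of the sequences were complete reading frames. Several sequences of 1 locus can carry the same signature.

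The sequences named in the text follow a rule fixed before the data were examined. It takes the members of the marker families (Piwi, Argonaute, Nanos, silicatein, tektin, dynein heavy chain, annexin), all of them up to 6 and otherwise the 4 most abundant. It also takes, for each comparison and direction, the member with the largest fold in each of the 10 families with the largest folds, among sequences past the threshold whose libraries do not overlap, and the 2 sequences with the largest rises and falls. All tested members of the added families for Piwi and Argonaute, silicatein, cathepsin, tubulin and glyceraldehyde-3-phosphate dehydrogenase were taken as well, but the text does not give the values of each. Identifiers are printed only for the largest rises and falls.

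The code was tested on simulated data. In 10 simulations of archeocytes against choanocytes over 14824 sequences, with 200 changed in each, 19.2% of changes of 1 on the log2 scale, 82.3% of changes of 2 and 90.8% of changes of 4 were recovered, and 5.7% of calls were false. In the simulated comparison of choanocytes with other cells, which held no change, 0 sequences were called. These shares hold for a simulation with few changed sequences and were not estimated for the share that differed here.

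Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 RPKM, quantile normalization, median centring, no trend in the variances, a fit of only the 2 fractions compared, a block for the replicate number, each library left out in turn, all stop-free frames, frames of at least 100 residues, and 1 sequence per locus. A limma voom fit on read numbers rebuilt from RPKM was added after the data were seen. The whole-sponge sample had no expression column in the files used and was not analysed here.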

Results

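RNA was measured in sorted cells of juvenile Ephydatia fluviatilis, a freshwater sponge grown from gemmules, the resting bodies from which it hatches. Flow cytometry gave 3 cell fractions with 2 libraries each. Archeocytes are the amoeboid stem cells of the sponge and give rise to its other cell types. Choanocytes are the flagellated collar cells that drive the water current and take up food particles. The remaining fraction, called other cells here, was a mixture of differentiated cells. Archeocytes and other cells were collected from sponges at stages 1 to 2, whereas choanocytes came from 7-day-old sponges at stage 5. Cell type and sponge age therefore changed together in each comparison that involved choanocytes. A further sample of whole juvenile sponges served as the source of the transcriptome; it had no expression column here and entered no comparison.

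Expression was given as RPKM, read numbers divided by the length of the coding sequence and by the library's total over the listed coding sequences. Of 17419 predicted coding sequences, 14824 had a mean of at least 1 RPKM and were tested. Reads on all listed sequences, estimated from the low values, numbered 13730000 and 11580000 in archeocyte replicates 1 and 2. They numbered 12270000 and 12580000 in choanocyte replicates 1 and 2, and 10650000 and 10980000 in the other cells. Across sequences, log2 values of the 2 replicates correlated with r = 0.99 in archeocytes, 0.973 in choanocytes and 0.981 in other cells, and the standard deviation of their difference was 0.32, 0.54 and 0.42 on the log2 scale. Choanocyte replicate 1 lay above replicate 2 by a median of 0.20, where the medians of archeocytes and other cells were −0.05 and 0.05. Between fractions the same correlation was 0.654 for archeocytes and choanocytes, 0.773 for archeocytes and other cells and 0.782 for choanocytes and other cells. These correlations are across sequences, which are not independent replicates. The labels do not say that the 2 libraries of a fraction came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical. The files do not pair the sequence identifiers with gene names. Protein families were therefore recognised by conserved residue signatures, which mark a family and not one named gene. Levels are means ± SD in RPKM (n = 2 libraries per fraction), and fold changes are on the log2(RPKM + 1) scale, which understates the change of weakly expressed sequences.

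The comparison of archeocytes with choanocytes asked what sets the stem cells of this sponge apart from a specialised cell type. In the lists of RNA helicases, replication proteins and proteins with an RNA recognition motif given below, most sequences were higher in archeocytes. None of these lists passed the camera test with an estimated correlation. The sequence with a Piwi signature, the family of proteins that silence transposons with small RNAs and that marks stem and germ cells in many animals, stood at 43.7 ± 1.93 RPKM in archeocytes and 1.92 ± 0.912 in choanocytes. Its log2 fold change was 3.98 (SE 0.30, limma adjusted p = 3.13e-06). This planned Piwi signature also gave 1 hit in reversed residues, so its single hit is uncertain. A stricter signature for the C-terminus of Piwi and Argonaute proteins had 2 hits, the Argonaute sequence given next and another at 111 ± 1.56 against 8.30 ± 4.69 RPKM, a log2 fold change of 3.68 (SE 0.32, limma adjusted p = 7.75e-06). The Argonaute sequence did not pass, with 25.9 ± 0.559 RPKM in archeocytes and 20.6 ± 3.32 in choanocytes (log2 fold change 0.33, SE 0.21, limma adjusted p = 0.183).

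DEAD-box helicases, ATP-driven enzymes that unwind RNA and include the germline protein Vasa, were higher in archeocytes in 24 of 24 tested sequences, also when adjusted over the list alone, with log2 fold changes from 1.27 to 4.29 and a median of 2.77. The list passed limma's camera test at adjusted p = 3.84e-07 with a preset correlation, and had adjusted p = 0.918 with an estimated correlation. The member with the largest fold was at 62.9 ± 5.71 RPKM in archeocytes and 2.37 ± 1.19 in choanocytes (log2 fold change 4.29, SE 0.30, limma adjusted p = 2.06e-06). DEAH helicases, which act in splicing and ribosome assembly, were higher in archeocytes in 11 of 13 sequences and lower in 0, with the same 11 and 0 adjusted over the list alone (median 1.72, camera adjusted p = 0.00609, and adjusted p = 0.918 with an estimated correlation). The MCM proteins, which form the helicase that licenses DNA replication, were higher in 6 of 6 sequences, also adjusted over the list alone. Their log2 fold changes ran from 2.11 to 3.57 (camera adjusted p = 0.00765, and adjusted p = 0.918 with an estimated correlation). The MCM sequence with the largest fold stood at 128 ± 2.40 RPKM in archeocytes and 10.0 ± 2.63 in choanocytes. Proteins with a strict RNA recognition motif, a signature added after the sequences had been seen, were higher in 20 of 23 sequences and lower in 2 (20 and 3 adjusted over the list alone, camera adjusted p = 0.00252, and adjusted p = 0.973 with an estimated correlation).

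Transcription factors went both ways. The homeobox list had 7 sequences higher in archeocytes and 5 lower of 18 tested (limma camera adjusted p = 0.795). Its largest archeocyte member reached 241 ± 1.42 RPKM in archeocytes against 14.7 ± 5.59 in choanocytes (log2 fold change 3.99, SE 0.26, limma adjusted p = 1.62e-06). The GATA factor was at 105 ± 9.74 against 7.19 ± 4.62 RPKM (log2 fold change 3.82, SE 0.39, limma adjusted p = 1.95e-05), and its fold change was 4.43 without choanocyte replicate 1 and 3.21 without choanocyte replicate 2. One forkhead factor was high in choanocytes, at 305 ± 96.2 RPKM against 5.80 ± 3.36 in archeocytes (log2 fold change −5.55, SE 0.33, limma adjusted p = 9.68e-07).

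In the lists of SRCR proteins, cadherins, tyrosine phosphatases and tyrosine kinases, more sequences were higher in choanocytes than were higher in archeocytes. Of 47 sequences with a scavenger receptor cysteine-rich (SRCR) domain, found in secreted and surface receptors, 34 were higher in choanocytes and 9 in archeocytes, or 35 and 9 adjusted over the list alone. Their median log2 fold change was −2.41 (limma camera adjusted p = 3.99e-05, and adjusted p = 0.918 with an estimated correlation). The SRCR sequence with the largest choanocyte excess had 171 ± 43.7 RPKM against 1.77 ± 0.453 in archeocytes. The list also held an exception of similar size, with 115 ± 10.9 RPKM in archeocytes and 2.74 ± 1.24 in choanocytes (log2 fold change 4.99, SE 0.27, limma adjusted p = 5.99e-07). Cadherins, calcium-dependent adhesion proteins, were higher in choanocytes in 10 of 16 sequences and in archeocytes in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00932, and adjusted p = 0.918 with an estimated correlation). Tyrosine phosphatases were higher in choanocytes in 29 of 55 and in archeocytes in 12, with the same counts adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.918 with an estimated correlation). Tyrosine kinases were higher in choanocytes in 70 of 161 sequences and in archeocytes in 38 (69 and 38 adjusted over the list alone). Their median was −0.30 (camera adjusted p = 0.0339, and adjusted p = 0.918 with an estimated correlation). One tyrosine kinase had 117 ± 3.95 RPKM in choanocytes and 1.62 ± 0.375 in archeocytes (log2 fold change −5.50, SE 0.23, limma adjusted p = 3.77e-07).

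The flagellar markers chosen for choanocytes were higher there in part of the sequences. Dynein heavy chains, the motors of flagellar beating and of transport along microtubules, had 5 sequences higher in choanocytes and 1 higher in archeocytes of 9 tested (camera adjusted p = 0.301). Without either archeocyte library the 5 fell to 3, and without choanocyte replicate 1 there were 3 and 2. The most abundant one stood at 45.3 ± 14.2 RPKM in choanocytes and 6.22 ± 0.502 in archeocytes (log2 fold change −2.65, SE 0.30, limma adjusted p = 4.33e-05). The one higher in archeocytes, at 29.3 ± 0.651 against 6.96 ± 4.67 RPKM, shared its contig with 2 overlapping reading frames, whose reads could not be told apart. Its log2 fold change of 2.07 was 2.70 without choanocyte replicate 1 and 1.43 without choanocyte replicate 2. Tektin, a structural protein of the flagellar shaft, had 79.9 ± 14.1 RPKM in choanocytes and 36.8 ± 1.17 in archeocytes (log2 fold change −1.09, SE 0.21, limma adjusted p = 0.00124). Annexins, calcium-dependent membrane-binding proteins, had 2 of 6 sequences higher in choanocytes and 0 in archeocytes (camera adjusted p = 0.359). The most abundant annexin had 3360 ± 662 against 1620 ± 43.2 RPKM (log2 fold change −1.04, SE 0.23, limma adjusted p = 0.00283). Of 4 tubulins found with an added strict signature, too few for a list test, none was higher in choanocytes. Their log2 fold changes of archeocytes over choanocytes were 0.67, 1.68, 0.17 and 1.11 (limma adjusted p = 0.00488, 1.63e-05, 0.285 and 0.00435). The first call was lost after median centring (limma adjusted p = 0.28) and quantile normalization (limma adjusted p = 0.847). It was also lost without archeocyte replicate 1 (log2 fold change 0.68) or archeocyte replicate 2 (log2 fold change 0.67).

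The largest rises in archeocytes over choanocytes were those of m.31020, which carried none of the signatures (375 ± 49.2 against 3.62 ± 2.96 RPKM, log2 fold change 6.50, SE 0.38, limma adjusted p = 8.44e-07), and m.16184, which carried the cathepsin signature (1200 ± 138 against 20.8 ± 13.5 RPKM, log2 fold change 5.94, SE 0.36, limma adjusted p = 1.05e-06). Without choanocyte replicate 1 these fold changes were 7.21 and 6.62, and without choanocyte replicate 2 they were 5.80 and 5.26. The largest falls were those of m.21792 (0.325 ± 0.346 against 573 ± 106 RPKM, log2 fold change −8.77, SE 0.27, limma adjusted p = 1.93e-07) and m.25097 (0.450 ± 0.255 against 314 ± 127 RPKM, log2 fold change −7.72, SE 0.52, limma adjusted p = 1.79e-06).

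In all, 10285 of 14824 tested sequences (69.4%) differed between archeocytes and choanocytes at a limma adjusted p under 0.05. Of these, 5675 were higher in archeocytes and 4610 in choanocytes, and 2568 and 1576 differed at least 4-fold. The authors' deposited table listed 11034 of all 17419 sequences at an FDR under 0.05, 5597 higher in archeocytes and 5437 in choanocytes. Among the 14824 tested sequences it called 10493, and 9784 were called in the same direction by both, and 0 in opposite directions. Of the 28 planned lists 11 passed the camera test, and with an estimated correlation 0 did. The tyrosine kinase call was lost without archeocyte replicate 1 (adjusted p = 0.0652).

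**Figure D1:**
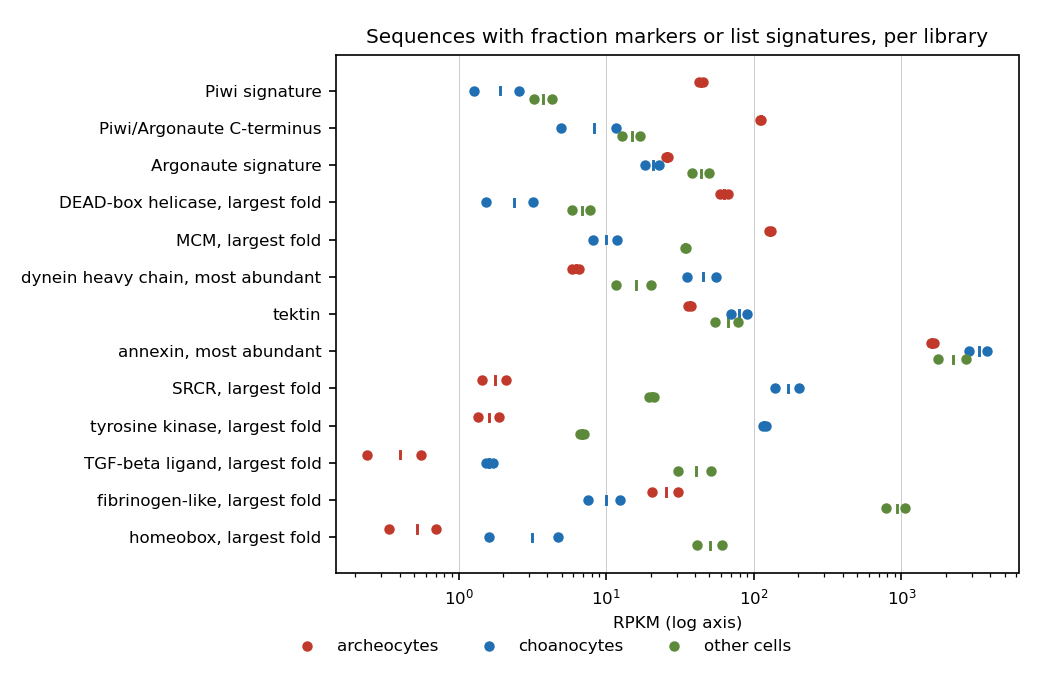
RPKM (log axis) of 13 sequences in each of the 6 libraries; points are libraries, bars the mean of the 2 libraries, and colours the 3 fractions. The Piwi, DEAD-box and MCM sequences lie to the right in archeocytes, the most abundant dynein heavy chain (45.3 RPKM) in choanocytes, and the TGF-beta ligand (40.9 RPKM) and fibrinogen-like sequence (927 RPKM) in other cells.

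The comparison of archeocytes with other cells asked how the stem cells differ from a mixture of differentiated cells taken from sponges of the same stages. The RNA helicases and replication proteins were again higher in archeocytes. DEAD-box helicases were higher in 23 of 24 sequences and lower in 0 (24 and 0 adjusted over the list alone), with a median log2 fold change of 2.15 (limma camera adjusted p = 1.41e-07, and adjusted p = 0.521 with an estimated correlation). The member with the largest fold had 43.6 ± 0.0849 RPKM in archeocytes and 3.71 ± 1.73 in other cells (log2 fold change 3.29, SE 0.32, limma adjusted p = 3.41e-05). DEAH helicases were higher in 10 of 13 sequences and lower in 0, also adjusted over the list alone (median 1.54, camera adjusted p = 0.00418, and adjusted p = 0.546 with an estimated correlation). MCM proteins were higher in 6 of 6, also adjusted over the list alone, by 1.00 to 1.87 on the log2 scale (camera adjusted p = 0.011, and adjusted p = 0.521 with an estimated correlation). The added RNA recognition motif list had 19 of 23 sequences higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.00497, and adjusted p = 0.576 with an estimated correlation). With 1 sequence per locus this last call was lost (adjusted p = 0.0502).

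The Piwi sequence had 3.74 ± 0.742 RPKM in other cells, a log2 fold change of 3.24 for archeocytes (SE 0.30, limma adjusted p = 2.76e-05). Of the 2 hits of the added Piwi and Argonaute C-terminus signature, the first had 14.9 ± 2.95 RPKM in other cells and a log2 fold change of 2.83 (SE 0.32, limma adjusted p = 8.3e-05). The other hit, the Argonaute sequence, was lower in archeocytes than in other cells, where it had 43.9 ± 7.89 RPKM (log2 fold change −0.73, SE 0.21, limma adjusted p = 0.0132). That call was lost without archeocyte replicate 1 (adjusted p = 0.0882), archeocyte replicate 2 (adjusted p = 0.0704) or other cells replicate 2 (adjusted p = 0.103).

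Among signalling proteins 228 of 430 sequences were higher in other cells and 65 in archeocytes. Among adhesion and matrix proteins 50 of 67 were higher in other cells and 6 in archeocytes. Of the 67, 47 were SRCR sequences and 16 cadherins, which are also given as lists of their own below, and 34 of the 50 were SRCR sequences. With an estimated correlation neither group passed (camera adjusted p = 0.521 for each). All 6 TGF-beta ligands, secreted signals that pattern animal embryos, were higher in other cells, also adjusted over the list alone, with log2 fold changes from −4.87 to −1.04 (limma camera adjusted p = 9.37e-04, and adjusted p = 0.521 with an estimated correlation). The one with the largest fold had 40.9 ± 14.3 RPKM in other cells and 0.400 ± 0.226 in archeocytes (SE 0.32, limma adjusted p = 7.32e-06). Tyrosine kinases were higher in other cells in 82 of 161 sequences and in archeocytes in 28 (83 and 28 adjusted over the list alone, median −0.64, camera adjusted p = 2.09e-04, and adjusted p = 0.546 with an estimated correlation). Serine/threonine kinases were higher in other cells in 78 of 156 and in archeocytes in 24 (80 and 24 adjusted over the list alone, camera adjusted p = 9.37e-04, and adjusted p = 0.521 with an estimated correlation). Small GTPases of the Ras and Rab type, molecular switches of signalling and vesicle transport, were higher in other cells in 29 of 52 and in archeocytes in 6, also adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.521 with an estimated correlation). Tyrosine phosphatases had 33 of 55 sequences higher in other cells and 7 in archeocytes (34 and 7 adjusted over the list alone, camera adjusted p = 3.59e-04, and adjusted p = 0.521 with an estimated correlation).

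SRCR proteins were higher in other cells in 34 of 47 sequences and in archeocytes in 6, also adjusted over the list alone (median −1.82, limma camera adjusted p = 6.57e-06, and adjusted p = 0.521 with an estimated correlation). The SRCR sequence with the largest fold differed strongly between the 2 other cells libraries, at 832 ± 725 RPKM against 8.46 ± 0.325 in archeocytes. Its log2 fold change of −6.12 (SE 0.51, limma adjusted p = 1.72e-05) was −7.15 without other cells replicate 1 and −5.08 without other cells replicate 2. Cadherins were higher in other cells in 12 of 16 and in archeocytes in 0, also adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.546 with an estimated correlation). A fibrinogen-like protein had 927 ± 195 RPKM in other cells and 25.6 ± 7.35 in archeocytes (log2 fold change −5.14, SE 0.27, limma adjusted p = 3.68e-06). Collagens, found with an added signature of long triple-helix repeats, split: 8 of 15 were higher in other cells and 4 in archeocytes, also adjusted over the list alone, over log2 fold changes from −5.26 to 3.00. The collagen median was −2.72 (camera adjusted p = 0.0341, and adjusted p = 0.715 with an estimated correlation). That call was lost with no filter on low values (median −0.74, adjusted p = 0.0514), with every frame searched (median −0.74, adjusted p = 0.117) and with 1 sequence per locus (median −2.72, adjusted p = 0.0502). The size of the median thus depends on which members are counted.

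Among transcription factors, 9 of 18 homeobox sequences were higher in other cells and 4 in archeocytes (10 and 4 adjusted over the list alone, limma camera adjusted p = 0.0253, and adjusted p = 0.521 with an estimated correlation). The homeobox sequence with the largest fold had 50.8 ± 13.8 RPKM in other cells and 0.520 ± 0.255 in archeocytes (log2 fold change −5.08, SE 0.40, limma adjusted p = 1.38e-05). The homeobox factor highest in archeocytes over choanocytes was also above its level in other cells, 25.8 ± 6.68 RPKM, by 3.19 on the log2 scale (SE 0.26, limma adjusted p = 1.66e-05). The GATA factor likewise stood at 10.7 ± 4.21 RPKM in other cells, a log2 fold change of 3.22 (SE 0.39, limma adjusted p = 1.11e-04). Forkhead factors had 6 of 9 sequences higher in other cells and 2 in archeocytes, also adjusted over the list alone (camera adjusted p = 0.0361, and adjusted p = 0.521 with an estimated correlation). The forkhead call was lost without choanocyte replicate 1 (adjusted p = 0.0623), choanocyte replicate 2 (adjusted p = 0.0608) or other cells replicate 2 (adjusted p = 0.0512), with a minimum mean of 5 RPKM (adjusted p = 0.11) and in a fit of the 2 fractions alone (adjusted p = 0.0646).

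Flagellar and contractile families were compared as well. Dynein heavy chains had 2 of 9 sequences higher in other cells and 0 in archeocytes (1 and 0 adjusted over the list alone, limma camera adjusted p = 0.329). Both calls were lost without archeocyte replicate 1 (adjusted p = 0.0599 and 0.135) or other cells replicate 1 (0.082 and 0.202), and the second also without archeocyte replicate 2 (0.0947). Tektin was at 66.7 ± 16.7 RPKM in other cells, a log2 fold change of −0.82 (SE 0.21, limma adjusted p = 0.00787). This call was lost without archeocyte replicate 2 (adjusted p = 0.0558) or other cells replicate 1 (adjusted p = 0.0689). Myosins were higher in other cells in 7 of 10 sequences, also adjusted over the list alone, and in archeocytes in 0 (camera adjusted p = 0.0308, and adjusted p = 0.521 with an estimated correlation). The myosin call was lost without archeocyte replicate 1 (adjusted p = 0.0518) and with 1 sequence per locus (adjusted p = 0.106). The annexin list did not pass (camera adjusted p = 0.139), although its second most abundant member had 1470 ± 148 RPKM in other cells and 279 ± 54.8 in archeocytes (log2 fold change −2.40, SE 0.17, limma adjusted p = 9.81e-06).

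The largest rises in archeocytes over other cells were those of m.5029 (1840 ± 175 against 93.8 ± 0.870 RPKM, log2 fold change 4.28, SE 0.24, limma adjusted p = 4.58e-06) and m.25747 (1980 ± 13.1 against 103 ± 12.9 RPKM, log2 fold change 4.26, SE 0.22, limma adjusted p = 3.6e-06). Each shared its contig with 1 overlapping reading frame, so their reads are uncertain. The largest falls were those of m.31900 (13.4 ± 0.318 against 2090 ± 1070 RPKM, log2 fold change −7.08, SE 0.42, limma adjusted p = 5.83e-06) and m.18698 (1.78 ± 0.368 against 340 ± 174 RPKM, log2 fold change −6.84, SE 0.32, limma adjusted p = 2.5e-06). None of these 4 carried a signature.

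In this comparison 8994 sequences (60.7%) differed at a limma adjusted p under 0.05, 4884 higher in archeocytes and 4110 in other cells, of which 1173 and 1085 differed at least 4-fold. The authors' deposited table listed 9369 of all sequences at an FDR under 0.05, 4801 higher in archeocytes and 4568 in other cells. It called 8962 of the tested sequences, and 8479 were called in the same direction by both and 0 in opposite directions. Of the 28 planned lists 19 passed, 5 higher in archeocytes and 14 in other cells, and 0 passed with an estimated correlation. The list of all cilium and cytoskeleton families, with 18 of 47 sequences higher in other cells and 6 in archeocytes (17 and 4 adjusted over the list alone, limma camera adjusted p = 0.0364, and adjusted p = 0.729 with an estimated correlation), was lost without archeocyte replicate 1 (adjusted p = 0.0518), without other cells replicate 1 (adjusted p = 0.15) and with 1 sequence per locus (adjusted p = 0.0639).

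**Figure D2:**
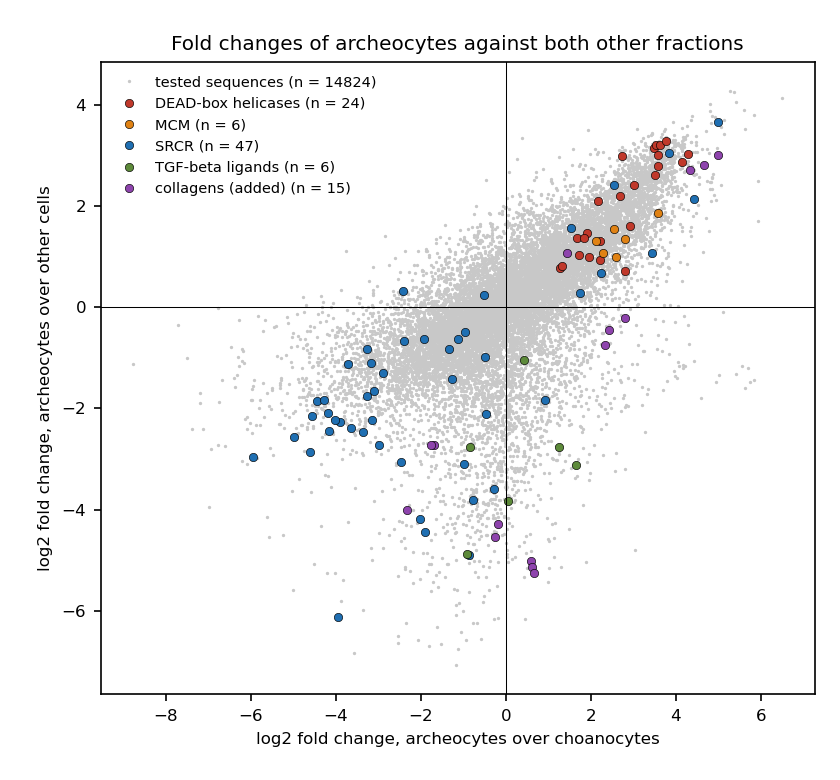
Log2 fold change of archeocytes over choanocytes (x axis) and over other cells (y axis) for 14824 tested sequences (grey) and 5 families (coloured). All 24 DEAD-box and 6 MCM sequences lie in the upper right part of the plot, and all 6 TGF-beta ligands below 0 on the y axis; both axes share the archeocyte libraries, so the points follow the diagonal in part by construction.

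The comparison of choanocytes with other cells set the collar cells against the remaining differentiated cells. Other cells had more RNA of TGF-beta ligands, homeobox factors, collagens and the silicateins of a strict signature. All 6 TGF-beta ligands were higher in other cells, also adjusted over the list alone, with a median log2 fold change of −3.92 (limma camera adjusted p = 0.012, and adjusted p = 0.999 with an estimated correlation). The ligand with the largest fold had 149 ± 7.66 RPKM in other cells and 4.61 ± 1.85 in choanocytes (log2 fold change −4.78, SE 0.29, limma adjusted p = 3.56e-06). Homeobox factors were higher in other cells in 13 of 18 sequences and in choanocytes in 3, also adjusted over the list alone (median −2.15, camera adjusted p = 0.0223, and adjusted p = 0.999 with an estimated correlation). The homeobox sequence with the largest fold had 239 ± 42.2 RPKM in other cells (log2 fold change −4.47, SE 0.38, limma adjusted p = 1.87e-05), with fold changes of −5.15 without choanocyte replicate 1 and −3.79 without choanocyte replicate 2.

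Collagens were higher in other cells in 14 of 15 sequences and in choanocytes in 0, also adjusted over the list alone (limma camera adjusted p = 6.72e-04, and adjusted p = 0.999 with an estimated correlation). Silicateins, the enzymes that build the siliceous spicules of sponges in sclerocytes, were recognised with an added strict signature. The planned signature gave 11 hits in reversed residues beside 18 hits and was left out of the list tests. All 8 strict silicateins were higher in other cells than in choanocytes, also adjusted over the list alone, with log2 fold changes from −3.04 to −1.16 (camera adjusted p = 0.0155, and adjusted p = 0.999 with an estimated correlation). Without choanocyte replicate 1 the fold changes of −3.04, −2.96, −2.09 and −1.83 became −3.75, −4.16, −2.75 and −2.42, and without choanocyte replicate 2 the first 3 became −2.33, −1.77 and −1.44. Without other cells replicate 1 or 2 the call at −1.16 was lost (adjusted p = 0.0606 and 0.0641) and 1 member fell below the minimum mean, which left 6 called. Against archeocytes 4 of the 8 were higher in other cells and 0 in archeocytes (camera adjusted p = 0.0968). Without either choanocyte library, and in a fit of the 2 fractions alone, 2 were higher in archeocytes and 5 in other cells; voom gave 1 and 4. The most abundant silicatein had 137 ± 12.7 RPKM in archeocytes, 29.4 ± 15.1 in choanocytes and 104 ± 2.38 in other cells. Of the 4 sequences that the rule named for the planned silicatein signature, this one was also a strict silicatein; the other 3 were found by the planned signature alone. One was higher in choanocytes, at 428 ± 25.1 against 74.6 ± 7.54 RPKM in other cells (log2 fold change 2.51, SE 0.15, limma adjusted p = 3.23e-06). The others did not pass between choanocytes and other cells. One had 519 ± 25.4 RPKM in archeocytes, above both other fractions (log2 fold changes 3.47 and 2.98, limma adjusted p = 2.58e-06 and 1.8e-05). It had 48.0 ± 19.9 RPKM in choanocytes and 65.0 ± 7.91 in other cells (log2 fold change −0.48, SE 0.25, adjusted p = 0.129, and −0.91 with adjusted p = 0.003 without choanocyte replicate 1). The last had 134 ± 3.46 RPKM in archeocytes (log2 fold changes 0.80 and 0.51, adjusted p = 8.7e-04 and 0.013). Its call over other cells was lost with quantile normalization (adjusted p = 0.0566), median centring (0.0803) and without archeocyte replicate 1 (0.105), archeocyte replicate 2 (0.0738) or other cells replicate 2 (0.0595). It had 76.6 ± 5.83 RPKM in choanocytes and 93.5 ± 3.51 in other cells (log2 fold change −0.29, SE 0.15, adjusted p = 0.125, and −0.40 with adjusted p = 0.0291 after quantile normalization). The fibrinogen-like protein named above had 9.97 ± 3.42 RPKM in choanocytes, a log2 fold change of −6.42 (SE 0.27, limma adjusted p = 1.29e-06).

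DEAD-box helicases, in part, and MCM proteins were lower in choanocytes than in other cells. DEAD-box helicases were higher in other cells in 13 of 24 sequences and in choanocytes in 0 (10 and 0 adjusted over the list alone, median −0.54, limma camera adjusted p = 0.0223, and adjusted p = 0.999 with an estimated correlation). All 6 MCM sequences were higher in other cells, also adjusted over the list alone (median −1.33, camera adjusted p = 0.0295, and adjusted p = 0.999 with an estimated correlation). The MCM sequence with the largest fold had 34.4 ± 0.679 RPKM in other cells against 10.0 ± 2.63 in choanocytes (log2 fold change −1.70, SE 0.20, limma adjusted p = 1.13e-04).

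In choanocytes, single members of several families stood out. A tyrosine kinase had 117 ± 3.95 against 6.86 ± 0.233 RPKM (log2 fold change 3.91, SE 0.23, limma adjusted p = 3.23e-06), while another had 2.24 ± 1.15 against 132 ± 37.1 RPKM (log2 fold change −5.38, SE 0.33, limma adjusted p = 3.84e-06). The tyrosine kinase list as a whole had 46 sequences higher in choanocytes and 53 in other cells of 161 (camera adjusted p = 0.997). A serine/threonine kinase had 636 ± 5.39 RPKM in choanocytes and 56.4 ± 12.9 in other cells (log2 fold change 3.49, SE 0.18, limma adjusted p = 2.12e-06). SRCR proteins had 21 sequences higher in choanocytes and 15 in other cells of 47 (camera adjusted p = 0.343). The most abundant dynein heavy chain was higher in choanocytes than in other cells (15.8 ± 5.91 RPKM) by 1.47 on the log2 scale (SE 0.30, limma adjusted p = 0.00291). Of the 9 dynein heavy chains 3 were higher in choanocytes and 1 in other cells (camera adjusted p = 0.543). Of the 3, 2 lost their calls without choanocyte replicate 1 (adjusted p = 0.139 and 0.119) and without other cells replicate 2 (0.202 and 0.191). The second of these also did without archeocyte replicate 1 (0.0517) or 2 (0.051) and in a fit of the 2 fractions alone (0.0504). Tektin did not pass between these fractions (log2 fold change 0.27, SE 0.21, limma adjusted p = 0.306).

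The largest rises in choanocytes over other cells were those of m.21792 (1.84 ± 0.0778 RPKM in other cells, log2 fold change 7.65, SE 0.27, limma adjusted p = 6.64e-07) and m.25097 (1.17 ± 1.65 RPKM in other cells, log2 fold change 7.37, SE 0.52, limma adjusted p = 7.56e-06), which also led the choanocyte side against archeocytes. The fold change of m.25097 was 6.50 without other cells replicate 1 and 8.24 without other cells replicate 2. The largest falls were those of m.23253 (6.14 ± 5.35 against 1400 ± 414 RPKM, log2 fold change −7.82, SE 0.50, limma adjusted p = 4.64e-06) and m.24278 (3.67 ± 3.32 against 641 ± 178 RPKM, log2 fold change −7.29, SE 0.42, limma adjusted p = 3.23e-06). Without choanocyte replicate 1 these were −8.67 and −8.08, and without choanocyte replicate 2 they were −6.97 and −6.49.

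Between choanocytes and other cells 8182 sequences (55.2%) differed at a limma adjusted p under 0.05, 3672 higher in choanocytes and 4510 in other cells, of which 810 and 1184 differed at least 4-fold. The authors' deposited table listed 8478 of all sequences at an FDR under 0.05, 4125 higher in choanocytes and 4353 in other cells. It called 8226 of the tested sequences, and 7646 were called in the same direction by both and 0 in opposite directions. Of the 28 planned lists 6 passed, all higher in other cells, and 0 passed with an estimated correlation; 3 passed without other cells replicate 1. The homeobox (adjusted p = 0.0501) and MCM (adjusted p = 0.0573) calls were lost without other cells replicate 1, and the DEAD-box call (adjusted p = 0.0586) without other cells replicate 2.

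**Figure D3:**
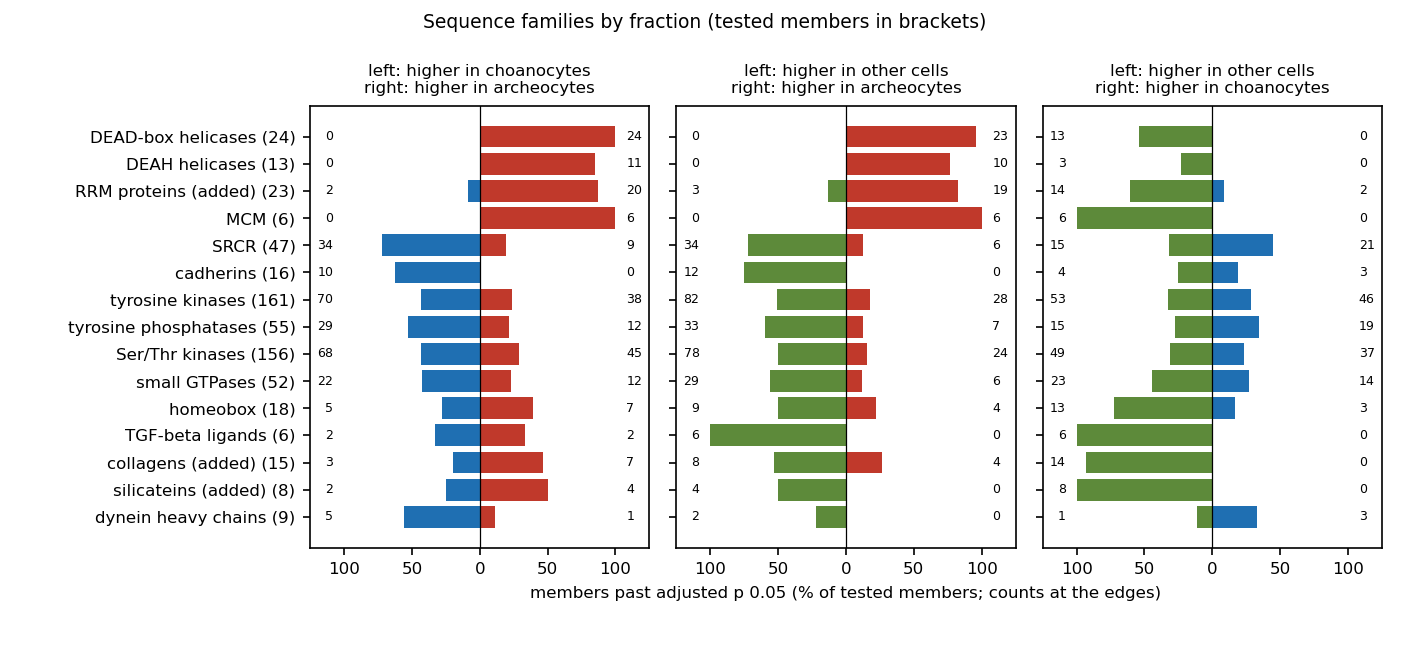
Share of the tested members of 15 families (x axis, percent) that passed adjusted p 0.05 in each direction, for the 3 comparisons; numbers at the edges are counts and numbers in brackets are members tested. DEAD-box helicases were higher in archeocytes than in choanocytes in 24 of 24 and than in other cells in 23 of 24, while all 6 TGF-beta ligands were higher in other cells than in either fraction.

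Sequences higher in 1 fraction than in both others were counted as enriched in it. Archeocytes had 4076 such sequences (27.5% of those tested), of which 1064 were at least 4-fold above both; choanocytes had 2907 (19.6%), with 675 at least 4-fold; and other cells had 1706 (11.5%), with 650 at least 4-fold. The gap between archeocytes and choanocytes depended on the scaling: median centring gave 3678 and 3622 enriched sequences and quantile normalization 3923 and 3517. Archeocyte-enriched sequences took in 23 of 24 DEAD-box helicases where 6.60 were expected from the share of all tested sequences (Fisher's exact test, adjusted p = 5.31e-11), 6 of 6 MCM proteins (adjusted p = 0.00225), 10 of 13 DEAH helicases (adjusted p = 0.00173) and 19 of 23 proteins of the added RNA recognition motif list (adjusted p = 1.13e-06). They took in 48 of 430 signalling proteins, where 118 were expected (adjusted p = 7.26e-15), and 0 of 16 cadherins (adjusted p = 0.0331). Choanocyte-enriched sequences took in 21 of 47 SRCR proteins, where 9.22 were expected (Fisher's exact test, adjusted p = 7.59e-04), 107 of 430 signalling proteins (adjusted p = 0.0261) and 0 of 24 DEAD-box helicases (adjusted p = 0.0311). A sequence can be enriched in only 1 fraction, so the 0 of 24 largely restates the 23 enriched in archeocytes and is no separate result on choanocytes. Other cells took in 6 of 6 TGF-beta ligands (Fisher's exact test, adjusted p = 2.85e-05), 42 of 161 tyrosine kinases, where 18.5 were expected (adjusted p = 4.54e-06), and 18 of 52 small GTPases, where 5.98 were expected (adjusted p = 1.03e-04). They also took in 9 of 18 homeobox factors (adjusted p = 4.86e-04), 8 of 15 collagens (adjusted p = 6.53e-04) and 4 of 8 silicateins (adjusted p = 0.0311). In all, 28 of 99 such tests, two-sided, passed after Benjamini-Hochberg adjustment. Fisher's test treats sequences as independent, which sequences of 1 locus are not.

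The 2 comparisons behind each enriched set share libraries. Lists drawn independently at the same sizes would overlap in 1870 sequences for archeocytes, 1142 for choanocytes and 1250 for other cells. In simulations without any effect, 0 sequences passed limma's adjusted p against both other fractions and 89.4 had an unadjusted p under 0.05 against both in the same direction, for archeocytes. Part of the excess over the independent draws can come from the shared libraries, which the simulations also share. Without any effect, adjusted calls are near 0 whether or not libraries are shared, so the simulated 0 does not measure that part. The median of all log2 fold changes was 0.12 for archeocytes over choanocytes, 0.06 for archeocytes over other cells and −0.13 for choanocytes over other cells. After each library was centred on its median, 4958 sequences were higher in archeocytes and 5647 in choanocytes, 4544 in archeocytes and 4551 in other cells, and 4412 in choanocytes and 3835 in other cells. The share of calls higher in the first-named fraction moved from 55.2% to 46.8%, from 54.3% to 50% and from 44.9% to 53.5%. No list call was lost or reversed by this centring.

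The groups of families that gathered these lists did not always pass where their members did. Signalling passed between archeocytes and choanocytes while its serine/threonine kinases did not (camera adjusted p = 0.109). Between choanocytes and other cells signalling did not pass (camera adjusted p = 0.946) while its TGF-beta ligands did (adjusted p = 0.012). The germline and RNA group held only the 24 DEAD-box helicases, the 13 DEAH helicases and the Argonaute sequence, since its other families had been left out. It therefore largely restates the helicase lists. The group was higher in archeocytes than in choanocytes in 35 of 38 sequences and lower in 0 (limma camera adjusted p = 8.14e-08). Against other cells it was higher in archeocytes in 33 and lower in 1 (camera adjusted p = 1.07e-07). It was lower in choanocytes than in other cells in 17 and higher in 0 (adjusted p = 0.0198). The DNA and chromatin group had 13 of 14 sequences higher in archeocytes in both comparisons (adjusted p = 5.68e-04 and 9.37e-04), and 9 lower and 0 higher in choanocytes than in other cells (adjusted p = 0.0223). That last call was lost without choanocyte replicate 1 (adjusted p = 0.0648), without other cells replicate 1 (adjusted p = 0.0681) and with every frame searched (adjusted p = 0.115). Adhesion and matrix proteins, of which 47 of 67 were SRCR sequences, were higher in choanocytes than in archeocytes in 45 and lower in 10 (camera adjusted p = 2.07e-05). They were higher in other cells than in archeocytes in 50 and lower in 6 (camera adjusted p = 8.99e-08). Signalling proteins were higher in choanocytes in 191 of 430 and in archeocytes in 109 (adjusted p = 0.0143), and higher in other cells than in archeocytes in 228 against 65 (adjusted p = 5.15e-06). Transcription factors had 21 of 44 sequences higher in other cells and 9 in archeocytes (adjusted p = 0.0074). With an estimated correlation the adjusted p was 0.918 for each of these calls against choanocytes, 0.521 or 0.546 for those of archeocytes against other cells, and 0.999 for those of choanocytes against other cells.

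Several lists did not pass between archeocytes and choanocytes: serine/threonine kinases (45 of 156 higher in archeocytes and 68 lower, limma camera adjusted p = 0.109), small GTPases (12 and 22 of 52, adjusted p = 0.196, and 0.0261 without choanocyte replicate 1), forkhead factors (2 and 4 of 9, adjusted p = 0.305) and myosins (3 and 5 of 10, adjusted p = 0.305). The same held for collagens (7 and 3 of 15, adjusted p = 0.521), silicateins (4 and 2 of 8, adjusted p = 0.686), TGF-beta ligands (2 and 2 of 6, adjusted p = 0.951) and the groups of transcription factors (13 and 15 of 44, adjusted p = 0.645) and cilium and cytoskeleton families (12 and 20 of 47, adjusted p = 0.196). Between choanocytes and other cells, DEAH helicases (0 and 3 of 13, adjusted p = 0.343), cadherins (3 and 4 of 16, adjusted p = 0.846) and tyrosine phosphatases (19 and 15 of 55, adjusted p = 0.846) did not pass. Nor did serine/threonine kinases (37 and 49, adjusted p = 0.947), small GTPases (14 and 23, adjusted p = 0.713), forkhead factors (2 and 3, adjusted p = 0.846), myosins (3 and 2, adjusted p = 0.997), annexins (2 and 2 of 6, adjusted p = 0.997) or the added RNA recognition motif list (2 and 14 of 23, adjusted p = 0.0972, and 0.0397 after quantile normalization). The groups of adhesion and matrix (24 and 23), signalling (116 and 146), transcription factor (10 and 18) and cilium families (13 and 10) had adjusted p = 0.737, 0.946, 0.311 and 0.846 there.

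In all 3 comparisons (archeocytes over choanocytes, archeocytes over other cells, choanocytes over other cells) the lists of kinesins (20 tested; limma camera adjusted p = 0.951, 0.841 and 0.997), zinc fingers with a C2H2 linker (21 tested; 0.708, 0.378 and 0.997) and ETS factors (5 tested; 0.359, 0.163 and 0.997) did not pass. Ubiquitins (11 tested; adjusted p = 0.645, 0.57 and 0.846) and the housekeeping and stress group (22 tested; adjusted p = 0.873, 0.831 and 0.947) did not pass either. A p that misses the threshold does not show that values were equal: kinesins had 8 sequences higher in archeocytes than in choanocytes and 6 lower.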

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

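Of the settings below, the voom fit was chosen after the data were seen. With each library left out in turn, 8416 to 10327 sequences differed between archeocytes and choanocytes (10285 with all libraries), 6437 to 9899 between archeocytes and other cells (8994) and 6261 to 8632 between choanocytes and other cells (8182). A fraction reduced to 1 library was assumed to vary like the others. Enriched sequences then numbered 3014 to 4365 in archeocytes, 2321 to 3088 in choanocytes and 1299 to 1946 in other cells. Under the remaining settings, voom included, the 3 comparisons gave 8516 to 10696, 7483 to 9802 and 7030 to 8527 sequences; voom gave 10185, 8760 and 7924. Enriched sequences were 3393 to 4266, 2574 to 3622 and 1308 to 1772; the 3622 in choanocytes came with median centring, which gave 3678 in archeocytes.

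Planned lists past the threshold numbered 10 to 12, 17 to 21 and 3 to 7 with a library left out, against 11, 19 and 6 with all. The 3, for choanocytes and other cells, came without other cells replicate 1; the cause was not tested. With an estimated correlation 0, 0 and 0 lists passed. That setting allows for members that vary together, and the estimate was 0.433 for DEAD-box helicases in place of 0.01. It also takes its p from the 3 residual degrees of freedom, which makes it hard to pass. The smallest unadjusted camera p of any list was 0.0985, for TGF-beta ligands in archeocytes against other cells. The loss of all list calls can therefore not be put down to members that vary together alone. Of 41 list calls, planned and added, 31 were kept under every other setting that tested the list. Of 223 calls on named sequences 192 were kept under every setting that tested the sequence, and 16 of the 31 lost were lost in a setting that keeps all libraries. Not all were tested in each setting: with a minimum mean of 5 RPKM, 264 of 270 values of named sequences were. A cathepsin with 1350 RPKM in archeocytes and 1340 in choanocytes had a log2 fold change of 0.01 (limma adjusted p = 0.943), which became −0.69 (adjusted p = 0.000924) under quantile normalization; the cause was not tested.

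Libraries of the same replicate number did not deviate together (r across sequences 0.007, 0.025 and −0.067). With 2 libraries per fraction this gives no sign of pairing by number but cannot exclude it. With the replicate number as a block 10108, 8765 and 7882 sequences differed, and 11, 19 and 6 planned lists passed. At an estimated 10650000 to 13730000 reads per library on the listed sequences, 2595 sequences had a mean under 1 RPKM and were not tested.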

Other observations

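Chaperones and cathepsins, of which the report gave only m.16184 and a group result, divided between the fractions. Of 8 HSP70 chaperones, 3 were enriched in archeocytes, 2 in choanocytes and 1 in other cells, and the list passed in no comparison (limma camera adjusted p = 0.951, 0.9 and 0.997). One had 1910 ± 455 RPKM in archeocytes, 92.3 ± 12.4 in choanocytes and 713 ± 120 in other cells (log2 fold change 4.35 over choanocytes, SE 0.20, limma adjusted p = 4.35e-07). Another went the opposite way, with 0.990 ± 0.679, 285 ± 62.2 and 5.24 ± 0.460 RPKM (log2 fold change −7.19, SE 0.29, limma adjusted p = 3.77e-07). The 2 HSP90 chaperones had 3620 ± 310 and 1570 ± 147 RPKM in archeocytes, 194 ± 74.3 and 51.3 ± 15.2 in choanocytes and 431 ± 37.4 and 361 ± 66.7 in other cells; the first shared its contig with 1 overlapping reading frame. Of 7 cathepsins, proteases of the lysosome found with an added signature, 3 were enriched in choanocytes and 1, m.16184, in archeocytes (camera adjusted p = 0.686, 0.262 and 0.162). The 3 had 2440 ± 658, 1670 ± 468 and 261 ± 58.7 RPKM in choanocytes, against 180 ± 41.4, 335 ± 45.1 and 118 ± 3.94 in archeocytes.

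Reverse transcriptases of LTR retroelements had 5 of 22 sequences higher and 6 lower in archeocytes than in choanocytes (limma camera adjusted p = 0.688). Against other cells 2 were higher and 9 lower (adjusted p = 0.0923, and 0.0453 without archeocyte replicate 2), and between choanocytes and other cells 2 and 8 (adjusted p = 0.543). The whole retroelement group had adjusted p = 0.731, 0.0923 and 0.543, the second of which was 0.0453 without archeocyte replicate 2. The 10 most abundant sequences took 6.99% of reads in each archeocyte library, 14.9% and 17.61% in the choanocyte libraries and 11.11% and 11.84% in the other cells libraries. A signature of light-harvesting proteins of algae had 0 hits, which does not exclude algal sequences without it.

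Of the tests below, those of sclerocyte carry-over, median centring, sponge stage, sequences no higher elsewhere and values less 2 standard errors were chosen after the results had been seen. Standard errors of medians and of their differences below came from 1000 redraws of the sequences, which takes sequences as independent. They do not measure the spread between libraries and can be too small.

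DEAD-box helicases were higher in archeocytes in 24 of 24 sequences against choanocytes and in 23 of 24 against other cells. With an estimated correlation the list passed in neither comparison (camera adjusted p = 0.918 and 0.521). Sponge age as the whole cause would leave archeocytes and other cells, from sponges of the same stages, alike, but their median log2 fold change was 2.15 (SE 0.46). With the trend on GC content and coding length taken out, the median moved from 2.77 to 2.48 (SE 0.37) over choanocytes and from 2.15 to 2.1 (SE 0.48) over other cells, and 24 and 22 of the 24 members stayed higher at adjusted p under 0.05. After median centring it was 2.48 (SE 0.35) over choanocytes, with 24 members higher. Less 2 standard errors these medians were 1.74, 1.14 and 1.78, above the 1 allowed. That margin counts members that vary together (estimated correlation 0.433) as independent. The bounds first set (1.5, and 2 for centring) were not all passed by 2 standard errors. With 24, 22 and 24 members still higher, the values argue against GC content, length or scaling as the whole cause in these libraries. A smaller part from them, age as part or all of the excess over choanocytes, and a difference between the cell types stay open.

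Silicateins, expected in the sclerocytes of the other cells fraction, were also found in archeocytes. Sclerocytes carried into the archeocyte sort in fixed proportion would give the 8 sequences 1 ratio, but their log2 fold changes spanned 4.27 (SE 0.67), with ratios of archeocytes to other cells from 0.103 to 2.38. Reads shared between near-identical members of these 8 were argued against by exact words of 50 bases. Of these words, 0% in a silicatein not lower in archeocytes occurred in one that was lower. Reads shared with sequences outside the 8 were not examined. Sclerocytes of another state in the archeocyte sort stay open, untested. No biological explanation was tested.

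Choanocyte replicate 1 lay above replicate 2 in 83.9% of the 1064 sequences enriched at least 4-fold in archeocytes and 80.8% of the 650 in other cells, against 43.3% of the 675 in choanocytes and 68.4% of the 6135 enriched in no fraction. Against non-enriched sequences of the same choanocyte level the excess was 0.04 (SE 0.017) and 0.1 (SE 0.023) on the log2 scale, but 61.3% of that reference was itself higher elsewhere, so a bound of 0.1 on it could not exclude carry-over of cells into replicate 1. Against sequences no higher elsewhere the excess was 0.12 (SE 0.0098), between the 0.1 expected at most from a loss of rare molecules in replicate 2 and the 0.3 expected at least from carry-over, so these cannot be told apart. One scaling factor for the library would move archeocyte-enriched and choanocyte-enriched sequences alike, within 0.2, and their medians differed by 0.48 (SE 0.024), or 0.43 less 2 standard errors. This argues against 1 factor as the whole cause, although a bound of 0.5 set beforehand was not reached. A biological difference between the libraries was not tested.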
